A study of Sus scrofa with 4 samples.

How the data were processed

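Single-cell RNA sequencing (10x Genomics 3' v3.1) was done on cells of pig meniscus in 4 libraries, 1 for each combination of lateral or medial meniscus and red or white zone. Per the labels, the synovium was removed, the zones were separated and the tissue was digested with pronase and then collagenase. The deposited matrices hold UMI counts per gene and barcode, which the authors made with Cell Ranger 6.1.2 against the pig genome Sscrofa11.1, with barcodes already filtered. Of 21280 features 14811 carried a gene symbol in the files, 688 were given one from the reference table of gene names, and 5787 kept their Ensembl identifier alone. The labels name no animals.

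Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 20% of UMIs from the 13 mitochondrially encoded genes, and barcodes called doublets by Scrublet, run per library, were removed. Of 27782 barcodes 27587 were kept. In the lateral red, lateral white, medial red and medial white library, 38, 0, 17 and 0 barcodes had under 200 genes, 15, 0, 21 and 0 exceeded the mitochondrial limit, and 105, 0, 1 and 0 were called doublets. Scrublet thus called almost none in 3 libraries, and a removal of the highest scores at the expected rate, of 265, 436, 374 and 488 barcodes, was added as an alternative after the data were seen. The kept cells held 9293515, 13719381, 11842837 and 14902274 UMIs.

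Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen with the library as batch, and 30 principal components and 15 neighbours were used for Leiden clustering at a resolution of 0.5 (scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15), without integration of libraries. Each of the 14 clusters was named by fixed marker lists. The score was the mean log2 fold of the markers over the mean of the other clusters with 20 CPM added, and a name needed a score of at least 1.0, 3 detected markers, a marker of its own among the top 10 genes and no other list with more of them there. Clusters that met no list stayed unnamed. The matrix class with the most cells, chondrocyte-like cells, was compared in full, and other classes with at least 50 cells in each library were compared between zones.

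Counts were summed per library, over all cells and per class. Genes passing filterByExpr were tested with edgeR 4.0.16 (R 4.3.3, TMM scaling, glmQLFit and glmQLFTest) for the zone with the meniscus as second term, and for the meniscus with the zone as second term, with 1 residual degree of freedom. The standard error is the log2 fold change divided by the root of the F statistic. P-values were adjusted by Benjamini-Hochberg, and a call means an adjusted p below 0.05. The TMM factors over all cells were 1.17, 0.808, 1.20 and 0.879. Lists of genes (32, fixed) were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and with fry. The estimated correlation and fry rest on the 1 residual degree of freedom. With it the estimated correlation could hardly pass any list, so it cannot tell which lists hold. In addition each list was adjusted over its own genes alone. Lists with under 3 tested genes were not tested.

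Genes are named where they have a symbol, a mean of at least 20 CPM and an adjusted p below 0.05, differ in the same direction in both pairs of libraries and are among the 10 largest changes per direction (5 in the other classes). Where under 6 genes passed, the 5 largest per direction are given as values with no call. Up to 4 genes with the lowest p are examples of a list, and genes fixed in advance (COMP, ACTA2, ACAN, COL2A1, COL1A1, SOX9, PECAM1) are given whatever their result. Of genes called between zones over all cells 1876 passed the naming rule, 1011 of them higher in the white zone. ACTA2 was not tested in chondrocyte-like cells, where its counts were too low. For a gene at 0 in a zone a floor of 3 counts over the zone gives the smallest fold, and for 1 to 3 counts the ratio has an exact counting interval. The shares of cells have exact binomial intervals, and where a class had 0 cells the text gives the share that 3 cells would make. These intervals and floors cover counting error only.

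The test was tested on simulated data with the depth of these libraries and the smooth trend of their dispersion. All libraries had the same mean profile, and few genes were changed. Spread particular to single genes and shifts in composition were left out, so the numbers do not give the error rate in the real data. For the zones over all cells it recovered 52 of 99 genes with a true 2-fold and 92 of 98 with a true 4-fold change, with 6 false calls among 12200 genes, and for the menisci 43 of 97 and 93 of 98 with 3 false calls. In chondrocyte-like cells it recovered 2 of 98 and 25 of 97 for the zones with 0 false calls, and 36 of 96 and 85 of 94 for the menisci with 22 false calls.

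The comparisons, the marker and gene lists and most alternatives were chosen before the data were examined. Those alternatives were DESeq2 1.42.0, no TMM, no low-count filter, no second term, each library left out, doublet calls kept, mitochondrial limits of 10% and none, thinning to the smallest library, a Leiden resolution of 1.0, and all matrix cells together. The removal of doublets at the expected rate, 30 neighbours, a fit without HPS5 and the unnamed gene that varies with it, and the comparisons in other classes with their rule on the library level were added after the data were seen. PRG4, HPS6 and the serum amyloid A genes were not analysed here, and reads were not used here. The result of 1 further gene is not reported here.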

Results

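Single cells of pig (Sus scrofa) meniscus, the fibrocartilage pad of the knee joint, were profiled from the lateral and the medial meniscus, each divided into a red and a white zone. In textbook anatomy the red zone is the vascularised outer part and the white zone the inner part without vessels. There were 4 libraries, 1 for each meniscus and zone, so each zone and each meniscus had 2 libraries. The lateral libraries are called replicate 1 and the medial libraries replicate 2 of their zone. The lateral red zone library held 5753 barcodes and 9666319 UMIs, the lateral white zone 7382 barcodes and 13719381 UMIs, the medial red zone 6840 barcodes and 11878284 UMIs, and the medial white zone 7807 barcodes and 14902274 UMIs. After filtering, 5596, 7382, 6802 and 7807 cells were kept in that order, with a median of 1455.5, 1495, 1492.5 and 1617 UMIs per cell. The labels name no animals. The p-values of genes therefore describe these 4 libraries only, in which lateral and medial differ by a single library per zone. With 1 residual degree of freedom, these p-values and the standard errors rest largely on a spread pooled over genes. A gene whose 2 pairs of libraries disagree can still have a very small p. The camera p-values at the preset correlation compare the genes of a list with other genes. They do not measure the spread between libraries, and genes are not independent replicates.

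Vascular and immune cells made up a larger share of both red zone libraries than of both white zone libraries. Endothelial-like cells, grouped by genes such as PECAM1 and VWF, were 17.8% of the lateral red (exact 95% binomial interval 16.8 to 18.8) and 16.2% of the medial red zone cells (15.3 to 17.1). In the white zone they were 2.66% of the lateral (2.30 to 3.05) and 3.87% of the medial cells (3.45 to 4.32). The white zone shares include a cluster of 27 lateral and 43 medial cells in which doublets are not excluded. Mural-like cells, which wrap vessels and carry ACTA2 and MYH11, were 17.1% and 14.9% of the lateral and medial red zone cells against 1.68% and 1.67% in the white zone. Myeloid-like cells, with the complement genes C1QA and C1QB, were 11.3% and 10.6% in the red zone against 1.00% and 0.704% in the white zone. T or NK cell-like cells numbered 151 and 140 in the lateral and medial red zone and 11 in the lateral white zone. None of 7807 medial white zone cells fell in this class, which allows a share of up to 0.0384%, taken here and below as 3 cells of the total. B or plasma cell-like cells numbered 142 in the lateral and 17 in the medial red zone. None was found in the white zone, which allows up to 0.0406% of lateral and 0.0384% of medial cells. Lymphatic endothelial-like cells, a class that also held Schwann-like cells, numbered 38 and 105 in the red zone, 0 in the lateral white zone, which allows up to 0.0406%, and 1 in the medial white zone. At a clustering resolution of 1.0 they numbered 17 and 80 in the red zone, with 21 and 23 cells set apart as Schwann-like.

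Cells outside these vascular and immune classes were 47.9% of lateral red, 54.4% of medial red, 94.5% of lateral white and 93.7% of medial white zone cells, a grouping chosen after the data were seen. They fell mainly into 3 matrix classes. Chondrocyte-like cells numbered 65, 4627, 45 and 2726 in the lateral red, lateral white, medial red and medial white libraries. Fibrochondrocyte-like cells, with COMP and CILP among their markers, numbered 231, 937, 102 and 4259 in the same order. Fibroblast-like cells numbered 2327, 223, 3518 and 113. The borders between the matrix classes moved with the clustering, and chondrocyte-like cells of the lateral white zone ranged from 1011 to 5020 over the settings tried, so these numbers were not compared between zones. No test was made on the shares. An exact permutation of 2 against 2 libraries cannot go below 0.33, and the intervals cover counting error only. The digestion and the dissection can also set the shares, so they need not be those of the tissue.

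**Figure D1:**
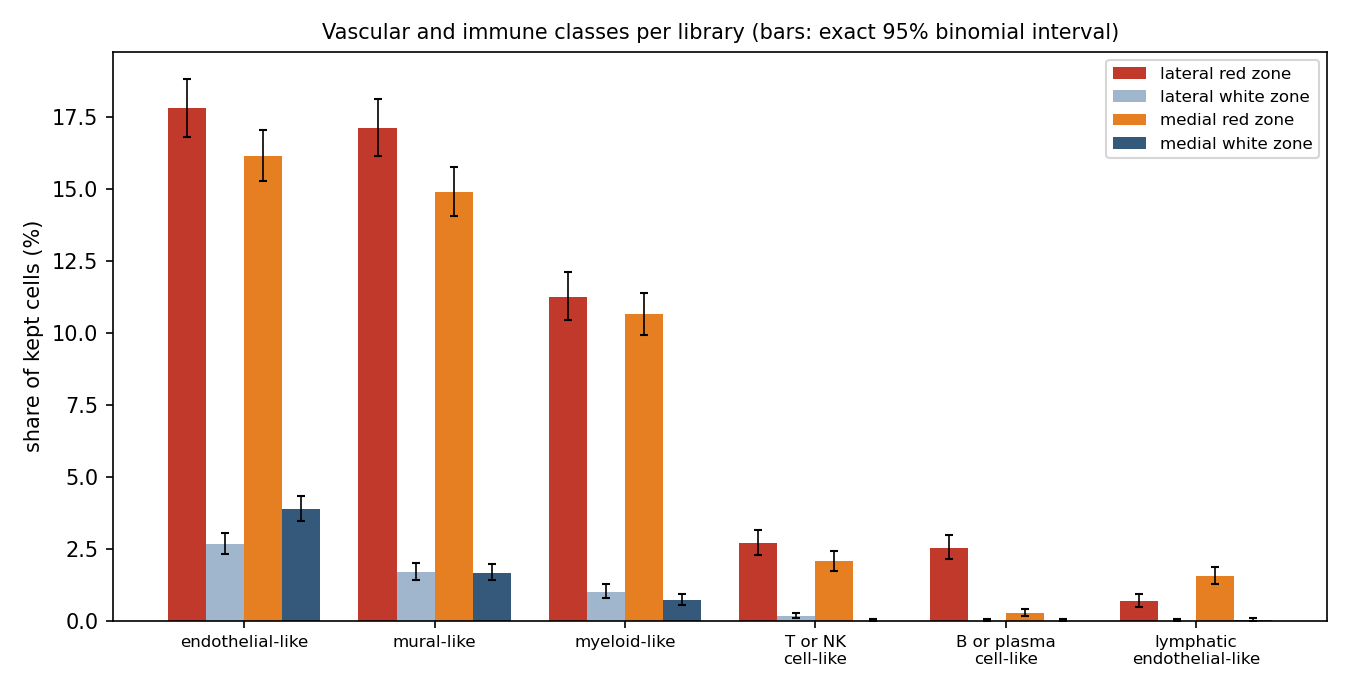
Share of kept cells (%) in each vascular or immune class for each of the 4 libraries, with exact 95% binomial intervals as error bars. The endothelial-like share was 17.8% and 16.2% in the red zone libraries and 2.66% and 3.87% in the white zone libraries.

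The comparison of the zones over all cells asked which genes differ between the inner and the outer meniscus. Cartilage genes were higher in the white zone. COL2A1 (ENSSSCG00000025523), the fibrillar collagen of hyaline cartilage, was at 5955 and 6737 CPM in the lateral and medial white zone against 342 and 63.6 CPM in the red zone, a log2 fold change of 5.91 ± 0.71 (SE, 2 libraries per zone; adjusted p = 0.000494). COL9A1 and COL11A2, its fibril partners, rose by 5.26 and 5.73 on the log2 scale. SNORC rose by 6.07 and CLEC3A by 6.25, both cartilage genes, and CILP, a protein of the cartilage matrix, by 5.73. MAL (ENSSSCG00000008115) had the largest rise among the genes named by the rule, at 6.59 ± 0.24 (adjusted p = 1.38e-05), and MAPK4 rose by 5.75. CP, which encodes the copper carrier ceruloplasmin, rose by 5.67, and LBP, which binds bacterial lipopolysaccharide, by 5.18. Of the other genes fixed in advance, ACAN rose by 3.48, SOX9, the transcription factor of chondrocytes, by 2.98, and COMP by 2.90 (adjusted p = 0.0047; no call by DESeq2).

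The genes with the largest falls in the white zone were as follows. MZB1 (ENSSSCG00000029239) had 918 and 216 UMIs in the lateral and medial red zone and 0 in the white zone, and was at least 512-fold lower there by library totals, with the floor set at 3 counts over the zone. JCHAIN, which joins immunoglobulin chains, fell by 7.30 on the log2 scale. CD209, a lectin of macrophages, had 1 UMI in the white zone, and its ratio of red to white was 2470 (exact 95% counting interval 443 to 97611). PI16, a marker of adventitial fibroblasts, had 3 UMIs there and a ratio of 1740 (595 to 8441), and the chemokine gene CCL26 had 1 UMI and a ratio of 1331 (238 to 52629). MFAP5, of the elastic microfibrils, fell by 9.18, SFRP2, a secreted WNT modulator, at -7.23, and MME at -7.09. The haemoglobin gene HBB fell by 6.85 and the chemokine gene CCL19 was lower at -6.27. ACTA2, the actin of smooth muscle, fell by 4.49 and PECAM1 by 1.57 (adjusted p = 0.00175). COL1A1, the main collagen of fibrous tissue, had a log2 fold change of -1.19 ± 0.56 with no call (adjusted p = 0.130; called by DESeq2 with adjusted p = 0.00197), at 20301 and 23537 CPM in the lateral and medial red zone and 3643 and 12784 CPM in the white zone.

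**Figure D2:**
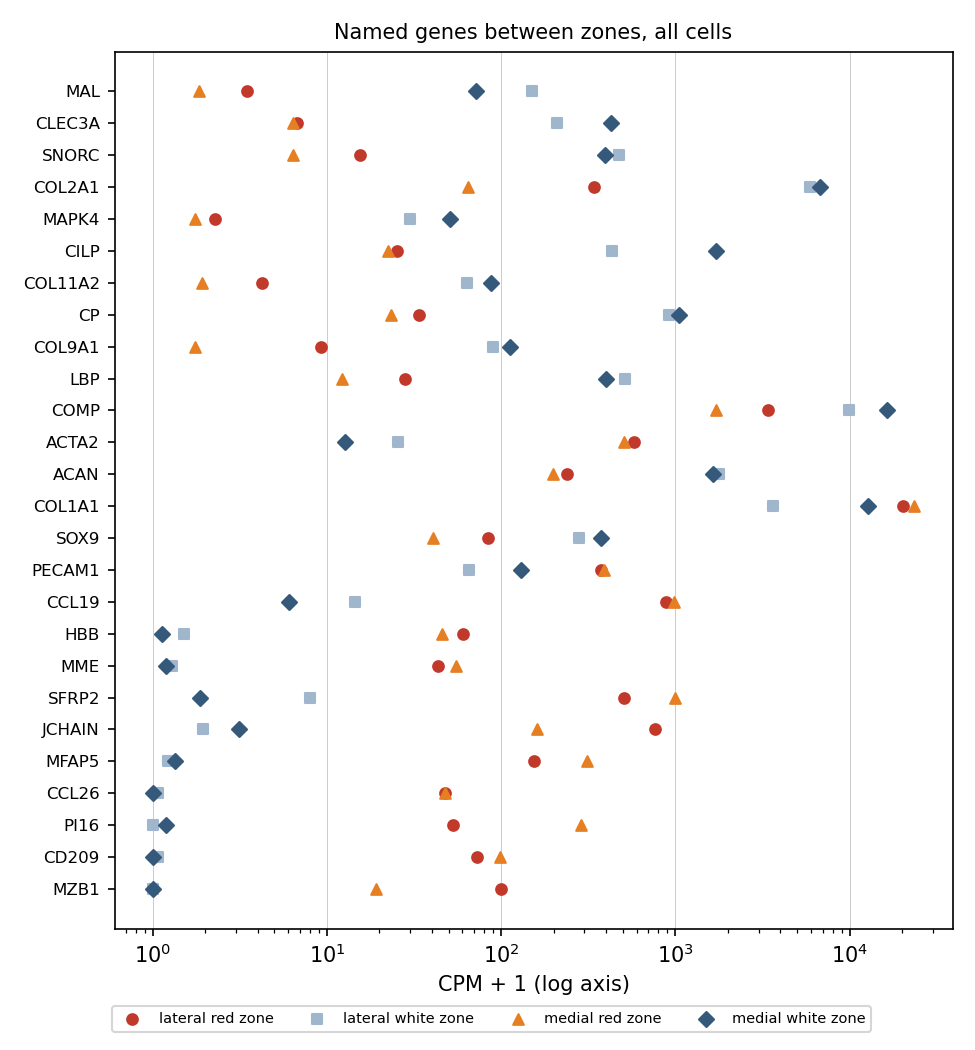
CPM plus 1 on a log axis of the genes named for the zone comparison over all cells, 1 symbol per library. COL2A1 was at 5955 and 6737 CPM in the white zone libraries against 342 and 63.6 CPM in the red zone, and CCL19 at 882.8 and 975 CPM in the red zone against 13.5 and 5.10 CPM in the white zone.

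At an adjusted p below 0.05, edgeR called 4954 of 12461 tested genes between the zones, 2211 higher and 2743 lower in the white zone, and DESeq2 called 3266. All 20 genes with the largest changes kept their call without any 1 library, but the count fell to 2848 without red zone replicate 1 and to 2450 without red zone replicate 2. Without TMM scaling the median log2 fold change shifted by -0.49, and 6049 genes were called, 903 higher and 5146 lower in the white zone. The log2 fold changes given here are relative to the TMM scaling, while the ratios and at-least folds use library totals without TMM. PRG4 was not analysed here.

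All 16 tested genes of the fixed cartilage matrix list rose in the white zone, and 16 also when adjusted over the list alone (camera adjusted p = 3.01e-13). COL9A3 rose by 4.99 and MIA by 4.70 on the log2 scale. Of 23 hypoxia and glycolysis genes 15 rose and 1 fell, and 16 rose and 1 fell adjusted over the list alone (adjusted p = 4.01e-06), among them the carbonic anhydrase CA9 by 3.41, BNIP3 by 2.31 and the glycolytic enzyme ENO1 by 2.07. Of 19 unfolded protein response genes 9 rose, or 11 adjusted over the list alone (adjusted p = 1.81e-05), such as CHAC1 by 4.01 and ASNS by 2.97, which respond to amino acid shortage. Of 57 ribosomal protein genes 14 rose and 1 fell, or 13 and 1 adjusted over the list alone (adjusted p = 3.55e-06). The calls of RPS21 and RPL22 in this list were lost without red zone replicate 1 and without red zone replicate 2, and that of RPL22 also without TMM. Of 20 leucine-rich proteoglycan and tendon-type genes 11 rose and 4 fell, or 12 and 4 adjusted over the list alone (adjusted p = 0.0072), with OMD up by 2.86 and LUM down at -3.06. TNMD of this list was at 0 in the white zone and at least 206-fold lower there. Of 10 hypertrophy and mineralisation genes 7 rose and 2 fell, the same numbers adjusted over the list alone (adjusted p = 0.00543), with SPP1 (osteopontin) at 4.23, IBSP at 3.82 and PTHLH at -6.11. Of 13 mitochondrially encoded genes 6 rose and 1 fell, the same numbers adjusted over the list alone (adjusted p = 0.014). With an estimated correlation these lists had adjusted p = 0.386, except the leucine-rich and tendon-type list with adjusted p = 0.480 and the ribosomal list with adjusted p = 0.531.

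Most vascular and immune marker lists, though not the B or plasma cell list, fell in the white zone. The shares of the vascular and immune classes that were found were smaller there. No cluster was named for mast cells, so their share is not known. The mast cell list had the second highest score in the larger endothelial-like cluster. Of 15 endothelial markers 14 fell and 1 rose, the same numbers adjusted over the list alone (camera adjusted p = 2.57e-06), with VWF at -3.27 and CLDN5 at -2.62. Of 15 mural markers 12 fell and 2 rose, the same numbers adjusted over the list alone (adjusted p = 4.18e-05), such as MYH11 at -4.02. Of 13 myeloid markers 12 fell (adjusted p = 5.76e-10), such as C1QA at -3.97 and MRC1 at -3.95. All 8 T or NK cell markers (adjusted p = 3.44e-05), all 6 lymphatic markers (adjusted p = 0.000379) and all 3 mast cell markers (adjusted p = 0.00848) fell, and 5 of 6 MHC class II genes (adjusted p = 0.00109), with SLA-DQB1 at -3.45. The counts of these lists from myeloid to MHC class II were unchanged when adjusted over the list alone. Of the 6 Schwann cell markers 5 fell and ERBB3 rose by 1.57, the same numbers adjusted over the list alone (adjusted p = 0.0183). With an estimated correlation these lists had adjusted p = 0.386, and the lymphatic list adjusted p = 0.389.

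Lists of response, basement membrane, protease and cell cycle genes also tested lower in the white zone, though not every member fell. Of 23 immediate-early and heat-shock genes 15 fell and 1 rose, or 16 and 3 adjusted over the list alone (camera adjusted p = 0.000237), including HSPA6 at -2.66 and ATF3 at -2.62. Of 23 inflammatory cytokines and NF-kappaB targets 15 fell and 3 rose, or 16 and 3 adjusted over the list alone (adjusted p = 0.000237), including IL6 at -4.49 and CXCL12 at -4.65. Of 21 interferon response genes 15 fell, or 16 adjusted over the list alone (adjusted p = 4.36e-06), such as ISG12(A) at -3.23. Of 13 basement membrane genes 11 fell and COL15A1 rose by 2.08, the same numbers adjusted over the list alone (adjusted p = 0.000237). Of 20 matrix proteases and inhibitors 10 fell and 4 rose, or 11 and 4 adjusted over the list alone (adjusted p = 0.00522), with the aggrecan-cleaving ADAMTS4 at -4.62 and the plasminogen activator PLAU at -5.07. Of 16 cell cycle genes 6 fell and 2 rose, or 8 and 2 adjusted over the list alone (adjusted p = 0.0252), with TOP2A at -2.21. Without TMM the cell cycle list (adjusted p = 0.0752) and the Schwann list (adjusted p = 0.0813) did not pass. With an estimated correlation these 6 lists had adjusted p = 0.386. The counts of calls within single classes did not all show these falls. Of inflammatory genes 7 of 20 rose and 1 fell in myeloid-like cells. In endothelial-like cells 0 of 17 rose and 6 fell, and in mural-like cells 2 of 18 rose and 8 fell. Of interferon genes 3 of 21 rose and 0 fell in endothelial-like cells, and 0 of 19 rose and 2 fell in myeloid-like cells. Of basement membrane genes 2 of 12 rose and 0 fell in endothelial-like cells, and 2 of 13 rose and 1 fell in mural-like cells. These counts were not limited to genes whose level in the class reached that of the whole library, so RNA of other cells can enter them. In myeloid-like cells 7 of 8 cartilage matrix genes rose by the same count. The endothelial-like counts include a cluster found in the white zone alone, in which doublets are not excluded. The interferon genes CXCL10 and RSAD2 were among the top genes of that cluster. Of all 29 lists tested, 21 passed camera, 0 passed with an estimated correlation (0 also at an unadjusted p below 0.05), and fry called the immediate-early list alone (adjusted p = 0.00828). With 1 residual degree of freedom the estimated correlation could hardly pass any list, here and below, so it cannot tell which camera results hold.

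The remaining 8 tested lists did not pass in this comparison. Fibrous matrix genes went both ways, 8 of 30 up and 10 down, or 9 and 11 adjusted over the list alone (camera adjusted p = 0.414). Of the skeletal patterning transcription factors 6 of 19 rose and 2 fell (adjusted p = 0.122), and of the TGF-beta and BMP genes 10 of 32 rose and 9 fell (adjusted p = 0.176). Of the WNT genes 7 of 22 rose and 9 fell (adjusted p = 0.967). The IGF and FGF list, with 7 of 15 up and 3 down (adjusted p = 0.363), had a median of -0.17 against an upward direction of its test. Of the lubrication and superficial zone genes 5 of 11 rose and 3 fell (adjusted p = 0.182). The B or plasma cell list (adjusted p = 0.180) and the adipocyte list (adjusted p = 0.390) each had 1 of 3 genes up and 2 down. The erythroid (1 tested gene), neutrophil (2) and skeletal muscle (1) lists were too short for a test. Adjusted over the list alone, the TGF-beta and BMP list had 11 up and 9 down, and the other short lists kept their numbers.

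The difference between white and red zone was similar in both menisci. Across 12461 genes the log2 difference in the lateral meniscus correlated with that in the medial meniscus at Pearson r = 0.876 and Spearman rho = 0.817, and 83.2% of genes had the same sign. For SNORC the differences were 5.02 in the lateral and 6.15 in the medial meniscus, and for MFAP5 -8.66 and -9.28. The 2 pairs of libraries share no library, but genes are not independent replicates, so no p-value is given.

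**Figure D3:**
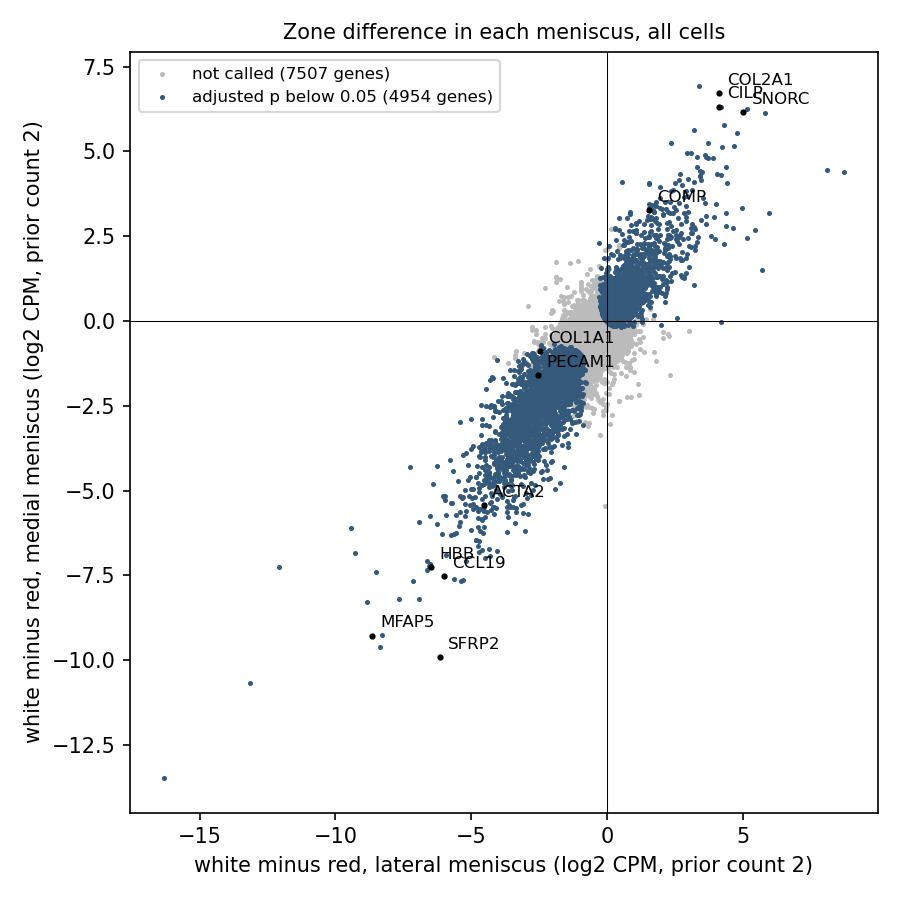
White minus red zone difference in log2 CPM (prior count 2, no TMM scaling) of each gene in the lateral meniscus (x axis) and the medial meniscus (y axis), over all cells, with called genes in blue. The differences of the 12461 genes correlated at r = 0.876.

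The comparison of the menisci over all cells asked which genes differ between the medial and the lateral side. PI16 was higher in the medial meniscus by 2.44 ± 0.26 on the log2 scale (adjusted p = 0.0381), at 285 CPM in the medial and 51.9 CPM in the lateral red zone but at 3 and 0 UMIs in the white zone. WIF1, a secreted WNT inhibitor, was lower by -1.67 ± 0.19 (adjusted p = 0.0414), at 25.03 and 4.22 CPM in the medial white and red zone against 69.4 and 14.1 CPM in the lateral. At a clustering resolution of 1.0 a cluster with PI16 and SFRP4 among its top genes held 282 lateral and 1226 medial red zone cells. An unnamed cluster with WIF1 among its top genes held 49 and 1156 lateral red and white zone cells against 6 and 168 medial ones. Differences in the cell mix between the menisci can thus enter both values and were not separated from differences within cells. The next largest values in the same direction in both zones carried no call. They were SFRP4 2.22, DKK3 1.80, ANGPTL7 1.66 and NPTX1 1.59 towards the medial side and MYBPH -2.20, CHI3L1 -2.12, SHOX2 -1.92 and HPS5 -1.75 towards the lateral side. The fixed genes had values between -1.19 and 0.93 with no call, COL2A1 at -1.19 (adjusted p = 0.786), COL1A1 at 0.93, ACTA2 at -0.67, PECAM1 at 0.45, SOX9 at -0.39, ACAN at -0.27 and COMP at -0.22.

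Of 12461 genes, 7 were called between the menisci by edgeR, 1 higher and 6 lower in the medial libraries (857 at an unadjusted p below 0.05), and 31 by DESeq2. Without any 1 library 0 genes were called (11 to 86 at an unadjusted p below 0.05), and PI16 and WIF1 lost their calls in each of these fits. These fits leave out the zone term and 1 zone of 1 meniscus, so the zone difference enters them and they do not test the menisci alone. The medial minus lateral differences of the red and the white zone correlated at r = 0.143 (rho = 0.120) across genes.

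No gene of the fixed lists passed over all genes in this comparison except WIF1, yet 12 of the 29 lists passed camera. The cartilage matrix list was lower in the medial libraries, with 0 of 16 genes called and 6 down adjusted over the list alone (camera adjusted p = 1.29e-08), such as COL9A3 at -1.47 and MIA at -1.46. Its members COL2A1 and SOX9 were lower in the red zone only, at -2.43 and -1.06, against 0.18 and 0.40 in the white zone. The zones of the other members are not given here. The myeloid list (0 and 4 down adjusted over the list alone; adjusted p = 1.53e-06), the inflammatory list (0 and 1 down; adjusted p = 1.86e-05), the hypoxia and glycolysis list (0 and 1 down; adjusted p = 0.000496), the hypertrophy list (0 and 0; adjusted p = 0.000753) and the B or plasma cell list (0 and 1 down; adjusted p = 0.000863) were lower too. The cell cycle list (0 and 5 up adjusted over the list alone; adjusted p = 4.93e-05) was higher in the medial libraries, with UBE2C at 1.99 and TOP2A at 1.10. Also higher were the endothelial list (0 and 0; adjusted p = 0.000399), the lymphatic list (0 and 2 up; adjusted p = 0.000753), the fibrous matrix list (0 up and 1 down; adjusted p = 0.000753), the leucine-rich and tendon-type list (0 and 0; adjusted p = 0.0139) and the mast cell list (0 and 1 up; adjusted p = 0.0139). With an estimated correlation 0 lists passed, with adjusted p = 0.681 for most of them and adjusted p = 0.730 for the leucine-rich list, and fry called 0 (0 and 2 at an unadjusted p below 0.05). The other 17 lists did not pass, with camera adjusted p between 0.0669 for the patterning transcription factors and 0.955 for the Schwann markers. Without TMM the patterning (adjusted p = 0.0467) and T or NK cell lists (adjusted p = 0.0315) passed as lower.

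Within chondrocyte-like cells, the matrix class with the most cells, fewer genes differed between the zones. HMOX1, the haem-degrading oxygenase, had 2 UMIs in the red zone and a ratio of white to red of 18.6 (exact 95% counting interval 5.14 to 154). STK17A had a ratio of 9.23 (3.15 to 44.8), WDR74 of 8.67 (2.96 to 42.1), PSMB7 of 12.2 (2.18 to 481) and SURF4 of 5.99 (2.05 to 29.1), each with 1 to 3 UMIs in the red zone. MSMP, IL18 and NXPH4 had 0 UMIs in the red zone and were at least 3.63-fold, 2.73-fold and 2.70-fold higher in the white zone, with the floor over the zone. MAL rose by 2.90 and OGN, a small proteoglycan, by 2.66. CRABP1, which binds retinoic acid, fell by 3.71 ± 0.41 (adjusted p = 1.22e-15), PTGFR by 3.21, the interferon gene ISG12(A) by 3.19, FAM180B by 2.33 and the proteoglycan LUM by 2.28. Also lower were the iron exporter SLC40A1 at -1.92, the WNT antagonist FRZB at -1.72, SPARCL1 at -1.59 and FOS at -1.39. The cartilage genes COL2A1 (0.09), ACAN (0.82), SOX9 (0.13) and COMP (0.23) had no call, nor had COL1A1 (-1.58, adjusted p = 0.0737). PECAM1 had 1 UMI in the red zone and a ratio of 0.940 (0.163 to 37.6). FRZB, COL2A1, ACAN and SOX9 are among the markers by which this class was named, and OGN, LUM, COMP and COL1A1 among those of the other matrix classes. CRABP1, also a top gene of fibroblast-like cells, ISG12(A), LUM and SPARCL1 were below the level of the whole library in both red zone libraries, CRABP1 at 290 and 416 CPM against 904 and 914 CPM. PTGFR was among the top genes of a fibroblast-like cluster at a clustering resolution of 1.0.

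Of 7959 genes, edgeR called 39 between the zones in this class, 27 higher and 12 lower in the white zone (482 at an unadjusted p below 0.05), and DESeq2 called 5, 2 higher and 3 lower. Without TMM the median shifted by -0.24 and 50 genes were called, 21 higher and 29 lower. The red zone held 65 and 45 of these cells with 127688 and 52876 UMIs, against 9438494 and 4589656 UMIs in the white zone. On simulated data of this size the test found 25 of 97 genes with a true 4-fold change. Without red zone replicate 1, red zone replicate 2 and white zone replicate 2 the counts were 15, 10 and 21, and of the named genes CRABP1 alone kept its call in all 4 such fits (highest adjusted p = 0.0199). The highest adjusted p in these fits was 0.747 for MSMP, 0.346 for IL18, 0.348 for NXPH4, 0.130 for HMOX1, 0.221 for PSMB7 and OGN, 0.0576 for STK17A, 0.149 for WDR74, 0.137 for MAL and 0.663 for SURF4. It was 0.998 for PTGFR, 0.213 for ISG12(A), 0.988 for FAM180B, 0.633 for LUM, 0.166 for SLC40A1, 0.386 for FRZB, 0.493 for SPARCL1 and 0.410 for FOS. The lateral and medial zone differences correlated at r = 0.133 (rho = 0.110) across genes. All 19 named genes lost their calls at a clustering resolution of 1.0, with 30 neighbours and with doublet calls kept, where 2, 2 and 3 genes were called in all, and CRABP1 turned to 0.31 with 30 neighbours. With the 3 matrix classes summed, 4024 genes were called.

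Of the 20 lists tested in this class 5 passed camera for the zones. The ribosomal list was higher in the white zone, with 0 of 57 genes called and 0 adjusted over the list alone (camera adjusted p = 9.42e-07). The interferon list was lower, with 1 of 14 genes down and 2 adjusted over the list alone (adjusted p = 0.000458). The hypoxia and glycolysis list was higher, with 1 of 21 up and 6 adjusted over the list alone (adjusted p = 0.00685), as were the IGF and FGF list with IGFBP5 up by 2.41 as its 1 call of 12, also adjusted over the list alone (adjusted p = 0.0242), and the unfolded protein response list with ASNS up by 2.31 as 1 of 19, and 4 adjusted over the list alone (adjusted p = 0.026). With an estimated correlation all 5 had adjusted p = 0.810, and fry called 0 (0 and 1 list at an unadjusted p below 0.05). The call of IGFBP5 held without each library but not at a clustering resolution of 1.0, and that of ASNS was lost without red zone replicate 2 (adjusted p = 0.261). The cartilage matrix list did not pass, with 0 of 15 genes called (camera adjusted p = 0.181). Most genes of that list are also markers by which this class was named, so its cells were grouped for like levels of them. This result therefore cannot tell whether the cartilage genes differ between the zones within chondrocytes. The 14 other lists did not pass, of which the hypertrophy list passed as lower without TMM (camera adjusted p = 0.0131). Lists of vascular and immune cells other than the endothelial and mural ones had too few tested genes.

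Between the menisci, chondrocyte-like cells of the medial side had less SHOX2, a transcription factor of limb patterning, by -4.64 ± 0.56 (adjusted p = 1.69e-12), at 1.31 CPM in the medial white zone and 93.2 CPM in the lateral white zone. PLCB1 (-2.34), the chemokine gene CXCL2 (-1.86) and FAM180B (-1.78) were also lower, and PLCB1 and CXCL2 were below the level of the whole library in both lateral libraries. Without a call, CILP (1.45), LUM (1.32), HMGCS1 (1.13), MAPK4 (1.05) and HMOX1 (1.05) had the largest values towards the medial side and CPXM2 (-2.05) was the next towards the lateral. COL2A1 (-0.08), COMP (-0.23), ACAN (0.23), SOX9 (0.18), COL1A1 (-0.82) and PECAM1 (-0.90) had no call. The patterning transcription factors were lower, with 1 of 15 genes called and 1 adjusted over the list alone (camera adjusted p = 0.0108). The inflammatory list was lower too, with 2 of 15 called and 2 adjusted over the list alone (adjusted p = 0.0108). With an estimated correlation both had adjusted p = 0.892, fry called 0 (0 lists by either at an unadjusted p below 0.05), and the other 18 lists did not pass. Without TMM the cartilage matrix (adjusted p = 8.7e-05), leucine-rich (adjusted p = 5.67e-06), mitochondrial (adjusted p = 0.0200) and ribosomal lists (adjusted p = 0.00914) passed as higher in the medial libraries.

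The count was 24 of 7959 genes by edgeR, 11 higher and 13 lower in the medial libraries (326 at an unadjusted p below 0.05), and 0 by DESeq2 (13 at an unadjusted p below 0.05). On simulated data of this size the same test made 22 false calls. Without red zone replicate 1, white zone replicate 1, red zone replicate 2 and white zone replicate 2 it was 6, 3, 46 and 13. The difference of SHOX2 was -0.39 in the red and -5.65 in the white zone, and the highest adjusted p without 1 library was 0.992 for SHOX2, 0.161 for PLCB1, 0.406 for CXCL2 and 0.706 for FAM180B. The differences of the red and white zone did not correlate across genes (r = -0.02, rho = -0.01). The small adjusted p of SHOX2 does not reflect how far its difference varied between the zones.

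The zones were also compared within the other classes with at least 50 cells per library. RNA of other cells can reach a droplet, so genes are named here only where their level in the class is at or above that of the whole library in both libraries of the higher zone, a rule set after the data were seen. In endothelial-like cells APLN, a peptide gene of sprouting endothelium, rose in the white zone by 5.65 ± 0.52 (adjusted p = 1.26e-05), DPP4 by 3.50, S100A4 by 3.42, ESM1, a gene of endothelial tip cells, by 3.24 and IMPA2 by 2.54. The fatty acid receptor gene CD36 was at 0 UMIs in the white zone and at least 43.7-fold lower there, FMO1 at least 20.8-fold and SERTM1 at least 19.6-fold. CCL26 had a red to white ratio of 233 (exact 95% counting interval 41.8 to 9222) and MGST1 of 60.9 (20.8 to 296). PECAM1 had no call in this class (adjusted p = 0.517), and the cartilage gene COL2A1, far below its library level there, rose by 6.41. The calls of IMPA2 (adjusted p = 0.106) and FMO1 (adjusted p = 0.0691) were lost without white zone replicate 2. In all, 568 of 7388 genes were called (250 higher, 318 lower in the white zone), 367 of them at or above the library level (121 higher, 246 lower). The class joined 2 clusters, and the smaller, of 27 lateral and 43 medial white zone cells and 0 red zone cells, had COL2A1 at 4270 CPM and ACAN at 1452 CPM. Doublets with matrix cells are not excluded in the smaller cluster. In the larger cluster alone 415 genes were called (143 higher, 272 lower), the 10 genes named here kept their calls, and COL2A1 rose by 2.33. DESeq2 called 134, and the count was 192 without white zone replicate 1 and 51 without white zone replicate 2.

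In mural-like cells the retinoic acid hydroxylase gene CYP26B1 rose in the white zone by 4.15 ± 0.27 (adjusted p = 1.72e-49), the laminin gene LAMC3 by 3.94, CCN3 by 3.62, the water channel gene AQP1 by 3.58 and SERPINE2 by 3.46. PDK4, STMN2, DKK2, CHRDL1 and DES, the intermediate filament of muscle, were at 0 UMIs in the white zone and at least 16.0-fold, 15.4-fold, 8.70-fold, 8.49-fold and 8.43-fold lower. An unnamed cluster outside this class had RGS5, CYP26B1, NOTCH3 and COL2A1 among its top genes. It held 30 and 31 white zone cells against 1 and 0 in the red zone. Its median was 3063 UMIs per cell, against 1345 in mural-like cells. Scrublet called 0 doublets in both white zone libraries, so doublets with matrix cells are not excluded among white zone mural-like cells. The mural-like class is not uniform either. At a clustering resolution of 1.0 its cluster with MYH11 and CNN1 among the top genes held 279 and 379 red zone cells against 18 and 12 white zone cells. Its largest cluster held 679 and 638 against 106 and 118. Of 7354 genes 531 were called (189 higher, 342 lower), 87 by DESeq2, and 410 were at or above the library level. Far fewer genes were called without red zone replicate 1, red zone replicate 2 or white zone replicate 2. These fits drop the meniscus term and leave 1 library in a zone, and those without a red zone replicate tested fewer genes. What the losses rest on was therefore not isolated. CYP26B1 and LAMC3 kept their calls (highest adjusted p = 0.0352), while the highest adjusted p was 0.0639 for CCN3, 0.0507 for AQP1, 0.108 for SERPINE2 and PDK4, 0.0996 for STMN2, 0.272 for DKK2, 0.185 for CHRDL1 and 0.252 for DES, each without 1 of the red zone libraries.

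In myeloid-like cells SPP1 rose in the white zone by 4.29 ± 0.35 (adjusted p = 7.68e-21), SMPDL3A by 3.47, GAREM2 by 4.41, ITGB8 by 3.89 and EDNRB by 3.82. The macrophage lectin CD209 was at 0 UMIs in the white zone and at least 68.1-fold lower, and the hyaluronan receptor LYVE1 at least 8.75-fold and PARM1 at least 3.99-fold. The homing receptor CCR7 was lower at -3.98, at a clustering resolution of 1.0 a cluster with CCR7 among its top genes held 189 and 168 red zone cells against 8 and 0 white zone cells, and ANKRD37 had a red to white ratio of 18.0 (exact 95% counting interval 3.17 to 713). Of 5646 genes 396 were called (182 higher, 214 lower), 98 by DESeq2 (60 higher, 38 lower), and 230 were at or above the library level (76 higher, 154 lower). The white zone held 74 and 55 of these cells, and the count was 134, 131, 35 and 50 without red zone replicate 1, white zone replicate 1, red zone replicate 2 and white zone replicate 2. SPP1, SMPDL3A and CD209 kept their calls in these fits. The highest adjusted p was 0.903 for GAREM2, 0.564 for EDNRB, 0.103 for ITGB8, 0.143 for LYVE1, 0.0827 for PARM1, 0.145 for ANKRD37 and 0.0511 for CCR7.

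**Figure D4:**
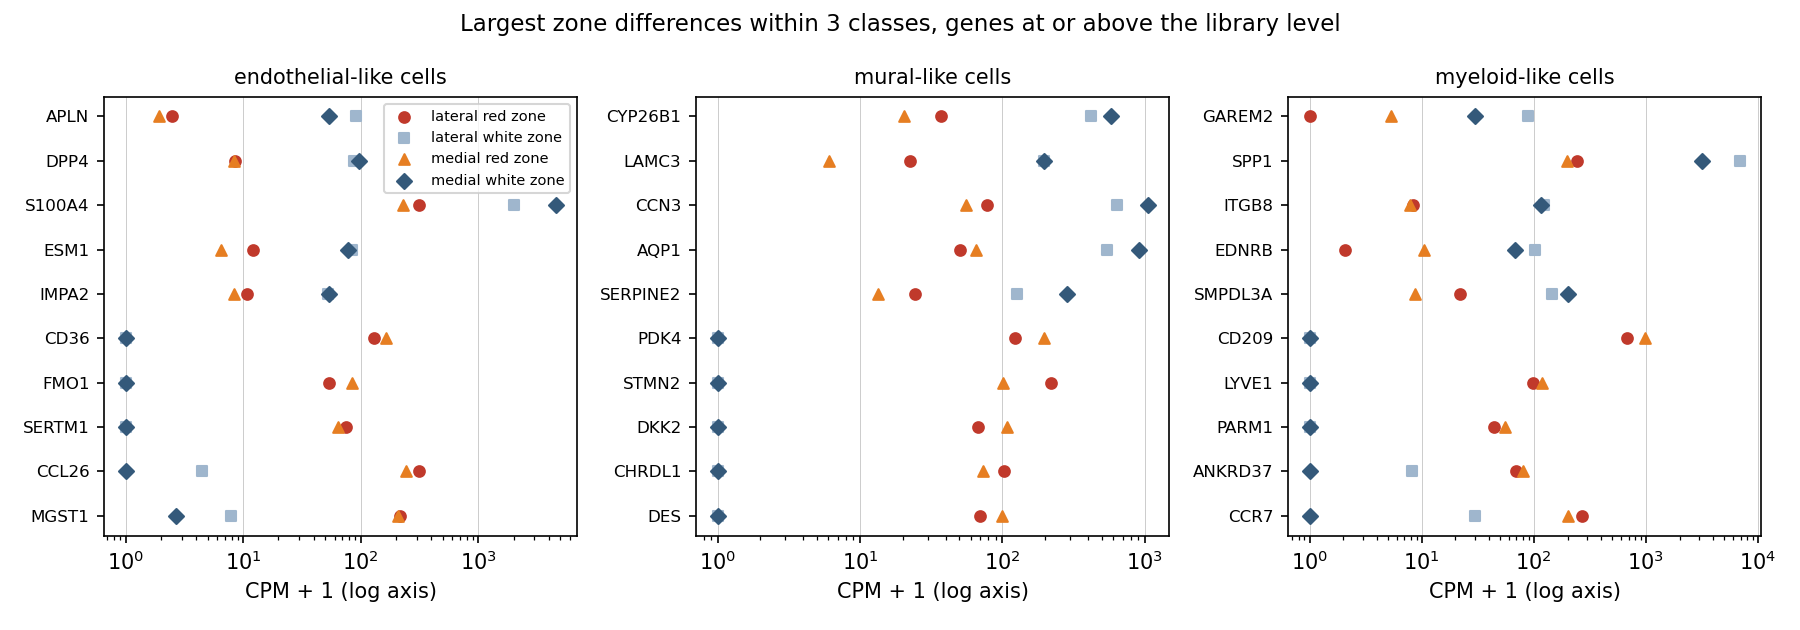
CPM plus 1 on a log axis of the genes with the largest zone differences in endothelial-like, mural-like and myeloid-like cells, 1 symbol per library. SPP1 in myeloid-like cells was at 6889 and 3133 CPM in the white zone libraries and at 241 and 195 CPM in the red zone libraries.

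The fibroblast-like class is not uniform, and at a clustering resolution of 1.0 its cluster with PI16 and MFAP5 among the top genes held 282 and 1226 red zone cells against 0 and 1 white zone cells. In fibroblast-like cells the collagenase gene MMP13 rose in the white zone by 5.24 ± 0.30 (adjusted p = 2.96e-07), F13A1 by 5.02, ADIRF by 3.53, SNX10 by 2.66 and SERPINE2 by 2.54. PI16, the complement gene C3 and the tendon gene TNMD were at 0 UMIs in the white zone and at least 57.9-fold, 8.27-fold and 7.11-fold lower. MFAP5 had a red to white ratio of 226 (exact 95% counting interval 40.5 to 8917) and C4A of 73.2 (20.2 to 605). In all 165 of 9268 genes were called (64 higher, 101 lower), 88 by DESeq2, and 71 without white zone replicate 2. The highest adjusted p without 1 library was 0.293 for SNX10, 0.0993 for PI16 and 0.0689 for TNMD, and the other 7 kept their calls, while TNMD lost its call with 30 neighbours too. In fibrochondrocyte-like cells DKK3 (2.38), HMOX1 (2.36), PSAT1 (2.13), ASPN (1.95) and OMD (1.91) rose in the white zone. ALDH1A1 (-3.06), ENO3 (-2.08), AMPH (-1.92), FRZB (-1.81) and RSPO2 (-1.80) fell, and COL1A1 fell by 1.48 (adjusted p = 2.16e-08). Here 96 of 6150 genes were called (44 higher, 52 lower), 24 by DESeq2 (15 higher, 9 lower), and 7, 204, 41 and 27 without red zone replicate 1, white zone replicate 1, red zone replicate 2 and white zone replicate 2. DKK3, PSAT1 and ENO3 lost their calls at a clustering resolution of 1.0 and with 30 neighbours, ALDH1A1 at the former and ASPN, AMPH and RSPO2 with the latter. Without 1 library HMOX1 and OMD kept their calls, and the highest adjusted p was 0.666 for DKK3, 0.190 for PSAT1, 0.120 for ASPN, 0.189 for ALDH1A1, 0.395 for ENO3, 0.783 for AMPH, 0.146 for FRZB, 0.616 for RSPO2 and 0.621 for COL1A1.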

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

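All tests in this part were chosen after the result was seen, except the test of the mix of matrix classes, whose prediction was written before it was run.

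Some genes differed in opposite directions between pairs of libraries. Over all cells the medial minus lateral difference of COL2A1 was -2.43 in the red and 0.18 in the white zone, a gap of 2.60 log2 units, that of SOX9 -1.06 and 0.40, a gap of 1.47, and that of COMP -0.998 and 0.72, a gap of 1.72. In chondrocyte-like cells the white minus red difference of COL2A1 was -1.18 in the lateral and 0.83 in the medial meniscus, and the gap of 2.01 is the same for its medial minus lateral difference. For COMP in these cells the values were -0.54 and 0.48 with a gap of 1.02. Each of these gaps rests on 4 single libraries, and the difference was not tested.

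Barcodes removed for having under 200 genes held much of the haemoglobin RNA. HBB made up 20.4% of the UMIs of the 38 such barcodes of the lateral red zone and 50.4% of those of the 17 of the medial red zone, which is 93.4% and 92.7% of all HBB UMIs of these libraries. The white zone libraries had 0 such barcodes. The difference was not tested.

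Cartilage matrix genes were called higher in the white zone within endothelial-like, mural-like and myeloid-like cells. RNA of matrix cells in droplets of other cells could give this. It predicts that none of the calls reaches the level of the whole library, and 0 of the 21 did in both white zone libraries. Matrix cells make up most of these libraries, so weaker expression by the cells themselves would give the same, and this result cannot decide. The median level of the calls in the lateral and medial white zone was 26.1% and 16.3% of the library in endothelial-like cells. It was 8.05% and 3.07% in mural-like and 13.1% and 17.0% in myeloid-like cells. Of all genes called higher in the white zone in these classes 53.5% (332 of 621) did reach the level of the whole library, which free RNA alone would not give. In endothelial-like cells a cluster found in the white zone alone adds to the cartilage calls, since in the larger cluster alone COL2A1 rose by 2.33 instead of 6.41 and ACAN had no call (adjusted p = 0.133). Doublets with matrix cells are not excluded in the cluster found in the white zone alone. Whether the cartilage calls hold any RNA of these cells themselves stays open.

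HPS5 took 13.05% of the UMIs of the lateral white zone library, more than any other gene. An event in that library alone is argued against by chondrocyte-like cells of the other libraries, whose lowest level was 37.7% of that in the lateral white zone. In both white zone libraries HPS5 correlated with LCN2 and LBP across matrix cells at r of 0.211 to 0.428. The median of the correlations with LCN2 and LBP exceeded that of all 149 and 291 compared genes of like level (percentile 100). In the lateral and medial red zone the percentile was 100 and 99.8. The cells were pooled over the matrix classes, and LCN2 and LBP were among the top genes of the chondrocyte-like cluster. HPS5 was higher in chondrocyte-like cells than over all cells too. It was at 147615 against 130492 CPM in the lateral and 55598 against 30559 CPM in the medial white zone. The percentile could therefore follow from the classes and decides nothing on the cause. The unnamed gene ENSSSCG00000013369, left out of the compared genes, had r of 0.859 and 0.7999 in the white zone. The correlation with LCN2 and LBP could also come from transcripts of the serum amyloid A genes nearby being counted for HPS5, SAA2 beginning 33950 bases from its end. A response of HPS5 itself could give it as well. The counts cannot tell these apart, and reads would be needed.

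Many more genes were called between zones over all cells than within chondrocyte-like cells. Fewer counts are not the whole cause, since all cells thinned to the counts of the class gave 884 calls of 8848 tested genes. Different shares of vascular and immune cells are not the whole cause either, since matrix cells alone gave 4024 calls, 81.2% of the number over all cells. A different mix of matrix classes might account for much of it, but the correlations of predicted with measured differences were 0.801 and 0.637, and the lower one falls short of the limit set before, so this stays open.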

How the results depend on the processing

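All alternatives marked as added were chosen after the data were seen. Fits without 1 library drop the second factor and leave 1 library in an arm, assumed to vary like the others, so their lost calls partly follow from fewer libraries. Elsewhere the cause was not tested. In chondrocyte-like cells the 127688 and 52876 red zone UMIs limit what can be called. Of the values of single genes and single lists under the alternatives, 3509 stayed the same, 110 were stronger, 489 weaker, 154 moved and 15 reversed. Named genes without an adjusted p from DESeq2 have no value for it.

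With DESeq2 3266 genes were called between zones over all cells and 31 between menisci, and 5 and 0 in chondrocyte-like cells. In the other classes it called 134 (endothelial-like), 88 (fibroblast-like), 24 (fibrochondrocyte-like), 87 (mural-like) and 98 (myeloid-like). Between the menisci over all cells the count was 24 without TMM, 264 without the low-count filter, 0 without the zone term, 3 with doublet calls kept, 17 at a mitochondrial limit of 10%, 14 with no limit and 4 when thinned. Of added settings, removal of doublets at the expected rate gave 35, and leaving out HPS5 and the unnamed gene that varies with it gave 38. The cause was not tested.

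Between zones in chondrocyte-like cells the count was 2 without the meniscus term, 3 with doublet calls kept, 5 at a mitochondrial limit of 10%, 4 with no limit, 7 when thinned, 2 at a resolution of 1.0, 4024 with all matrix cells together, and, added, 2 with 30 neighbours and 16 with doublets removed at the expected rate. Between menisci in these cells it was 13, 63, 4, 62, 1, 68, 76 and 130 under the same settings without the last. The cause was not tested.

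In the other classes a resolution of 1.0 gave 953 (endothelial-like), 265 (fibroblast-like), 26 (fibrochondrocyte-like) and 322 (mural-like) calls. With 30 neighbours fibroblast-like cells had 260 and fibrochondrocyte-like cells 17, and with doublets removed at the expected rate 375 and 200. Genes at or above the library level were 367 in endothelial-like, 53 in fibrochondrocyte-like and 230 in myeloid-like cells. The cause was not tested.

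Leaving out each library gave 2450 to 5096 calls between zones over all cells (2848 without red zone replicate 1, 2450 without red zone replicate 2) and 0 in every such fit between menisci. In chondrocyte-like cells it gave 10 to 38 between zones (15, 10 and 21 without red zone replicates 1 and 2 and white zone replicate 2) and 3 to 46 between menisci (6, 3, 46 and 13). The ranges were 51 to 520 in endothelial-like (192 and 51 without white zone replicates 1 and 2), 71 to 228 in fibroblast-like, 7 to 204 in fibrochondrocyte-like (7, 204, 41 and 27), 9 to 429 in mural-like (23, 9 and 99 without the red zone replicates and white zone replicate 2) and 35 to 134 in myeloid-like cells (134, 131, 35 and 50).

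For gene lists the estimated correlation gave 0 in all 4 comparisons, and fry gave 1 for zones over all cells and 0, 0 and 0 in the others. Both rest on 1 residual degree of freedom, with which the estimated correlation could hardly pass any list. The share outside vascular and immune classes was 55.9% of the medial red and 94.3% of the medial white zone at a resolution of 1.0, and 57.0% of the medial red zone with doublets removed at the expected rate. The endothelial-like share at a resolution of 1.0 was 2.18% (lateral white), 14.0% (medial red) and 3.22% (medial white), and 14.9% and 3.44% in the last 2 with doublets removed at the expected rate. The mural-like share was 2.09% (lateral white) and 2.05% (medial white) with doublet calls kept, and 2.10% and 2.08% with 30 neighbours. Among genes of at least 20 CPM the menisci correlated at 0.916 for the zones, the zones at 0.176 for the menisci, and the menisci in chondrocyte-like cells at 0.104. The cause was not tested.

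Some log2 fold changes turned sign. In fits without 1 library the dropped factor enters the contrast, so these turns can follow from the construction and say nothing on the compared factor alone. Over all cells between menisci PI16 turned to -6.53 without red zone replicate 2 and WIF1 to 0.418 without white zone replicate 1 (-3.80 without white zone replicate 2). In chondrocyte-like cells between zones CRABP1 turned to 0.312 and FOS to 0.246 with 30 neighbours, FOS to 0.0145 and LUM to 0.188 at a resolution of 1.0, and FAM180B to 0.338 without red zone replicate 1 (-3.59 without white zone replicate 1). With all matrix cells together FRZB was 0.470, IGF1 -1.43, IGFBP6 -1.15, OGN -0.167, PECAM1 -1.98 and SLC40A1 0.484. SHOX2 between menisci was 0.0313 without white zone replicate 2 (-6.35 without red zone replicate 2), and ACAN in mural-like cells -0.330 without white zone replicate 1 (2.22 without white zone replicate 2). For the turns under other settings the cause was not tested.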

Other observations

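No hypothesis was tested in this part, and the clusters described were chosen after they were seen. A cluster of 64 cells without a class name carried genes of dividing cells, NUSAP1 at 1064 CPM and TOP2A at 681 CPM, with CRABP2 at 612 CPM, and held 6, 4, 32 and 22 cells of the lateral red, lateral white, medial red and medial white library. A cluster of 1379 cells, also unnamed, held 49, 1156, 6 and 168 cells in the same order. It carried the WNT modulators WIF1 at 234 CPM and SFRP1 at 487 CPM, ENPP2, which encodes autotaxin, at 425 CPM, and the protease gene MMP3 at 1522 CPM.

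The 144 lymphatic endothelial-like cells carried MMRN1 at 1050 CPM, CCL21 at 473 CPM and PROX1 at 462 CPM. The 159 B or plasma cell-like cells, 142 of them lateral red, had JCHAIN at 15211 CPM and MZB1 at 1975 CPM. A cluster of 70 endothelial-like cells was found in the white zone alone, 27 lateral and 43 medial, with the matrix gene CILP among its top genes. It had 2532 UMIs per cell at the median, against 1199 in the larger endothelial-like cluster. Scrublet had called 0 doublets in both white zone libraries, so doublets with matrix cells are not excluded. With doublets removed at the expected rate no such cluster was found, and the white zone held 167 and 252 endothelial-like cells in place of 196 and 302. None was found at a clustering resolution of 1.0 either. There an unnamed cluster with PLVAP and PECAM1 among its top genes held 17 and 90 red zone and 30 and 46 white zone cells.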
